A study of Drosophila melanogaster with 24 samples.

How the data were processed

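RNA was sequenced from neuroblasts, the neural stem cells of the fly brain, of Drosophila melanogaster. The cells belonged to 2 lineages: the antennal lobe (AL), the primary olfactory centre, and the mushroom body (MB), a centre of olfactory learning. AL neuroblasts were taken at 24, 36, 50 and 84 h of larval life and MB neuroblasts at 24, 50 and 84 h of larval life and at 36 h in the pupa, with 3 libraries in each of the 8 groups. Per the labels, animals were kept at 25 °C and matched in age to within 2 h, about 30 brains were dissected and digested for 30 min, and GFP-positive cells were picked by an automated sorter. Between 89 and 121 cells were recorded per library. RNA was amplified with the NuGEN Ovation V2 system, libraries were made with the Encore kit of the same maker, and a fixed amount of ERCC spike-in RNA (mix 1) was added. The labels give the same 3 cell numbers (106, 108 and 101) for AL at 24 h and AL at 84 h.

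The authors deposited a table with one count per gene and library and a table of TPM (transcripts-per-million). Their notes name CASAVA, cutadapt 1.7.1, Bowtie2 2.1.0, STAR 2.4.0i and HTSeq 0.6.1p1, and the genome builds dm3 and mm10. Which step used which build, the annotation version, the filters and the strand setting are not given in the sources used here. The positions in the tables are dm3 positions and are printed as such. The deposited count table has 15437 rows: 15339 genes, 92 spike-in RNAs, 5 summary rows of HTSeq and 1 row without a name, which was left out. The deposited TPM values equal the counts divided by 1 length per gene and scaled per library. Over 852 genes with over 500 counts in every library this held with a coefficient of variation of at most 0.15%, so the TPM table carries no measurement of its own. For 232 genes the table gives no identifier or position, and 5 symbols that had been turned into dates were restored.

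Total counts per library over genes were 6.06 to 9.27 M in AL and 3.15 to 5.83 M in MB. A gene with 3 counts, the upper limit that a count of 0 allows, corresponds to 0.324 to 0.952 counts-per-million (CPM), depending on the library. Such limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Spike-in RNA took 0.315% to 0.945% of the counts of genes and spike-in together.

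The main test was edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood fit with robust estimation) in R 4.3.3, fitted to all 24 libraries with 1 mean per group. It tested 10324 genes, with a common biological coefficient of variation of 0.471, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. These p-values measure the spread between these libraries only, because the labels do not say whether libraries of a group came from separate cultures. The comparisons were change over the 4 ages in AL and in MB, 84 h against 24 h in each lineage, MB at 36 h in the pupa against 84 h, AL against MB over the matched ages (24, 50 and 84 h) and at each of them, and the difference between AL and MB in the change from 24 to 84 h. Log2 fold changes are given with their standard error (SE) and levels as mean CPM with standard deviation (SD). Each group has n = 3. Folds against a group with 0 counts were bounded with a floor of 3 counts per library. Against a group with 1 to 3 counts in all, the fitted log2 fold change depends on the prior count, and ratios of counts over scaled library totals are given with an exact 95% counting interval (Poisson) for mid, verm, Gasp and CG13023. The printed log2 values of hb in MB, of E(spl)m4-BFM and Hml, and of ems, Act57B, Cyp28a5 and vnd between lineages also rest on such a group and are fitted values only.

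The 20 gene lists were temporal factors, neuroblast identity and asymmetric division, Notch target E(spl) genes, mushroom body lineage transcription factors, antennal lobe lineage transcription factors, Hox genes, cell cycle, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, glycolysis, ecdysone response, heat shock and dissociation response, neuron markers, glia markers, ganglion mother cell and newborn neuron markers, haemocyte markers, fat body markers, programmed cell death, and dosage compensation and sex. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over 160 list tests), again with an estimated correlation, and with fry. Named genes were the 10 highest and the 10 lowest log2 fold changes among genes with an adjusted p under 0.05, at least 10 CPM in the higher group and every library of one side above every library of the other (within each age where ages were matched). For the difference between lineages they were the 5 highest and the 5 lowest with at least 10 CPM in 1 or more of the 4 groups. All temporal factors and up to 4 members of each other list with the smallest adjusted p were added in every comparison. The comparisons, the lists, this rule and the other settings named next were fixed before the data were examined.

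The results were also computed with DESeq2 size factors in edgeR, scaling by spike-in and cell number, no filter on low counts, a filter at 10 CPM, DESeq2 1.42.0, a fit on the groups compared alone, a replicate block, limma on log2(TPM + 1), leaving out each library, camera with an estimated correlation and fry. Settings chosen after the data were seen were a fit without ribosomal RNA genes and CR43283, libraries thinned to 3.15 M counts, and spike-in scaling without cell numbers. The test was also run on simulated data made from these libraries, in which 200 of 10324 genes were changed. For AL at 84 h against 24 h it found 25% of genes changed 2-fold and 55% of those changed 4-fold, with 4 false calls. For AL against MB at 84 h it found 24% and 53% with 6 false calls, for change over the 4 AL ages 26% and 62% with 5, and for the difference between lineages 11% and 41% with 4. In the real data 12.4% of genes were called for AL at 84 h against 24 h, a larger share than was changed in the simulation. With fewer changed genes the adjusted threshold is stricter, so the simulated shares may be too low for these data. A gene left uncalled here can still have changed by 2-fold or 4-fold. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

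Of 240 named genes with a position, 48 overlap another gene with counts. The strand setting is unknown, so reads of overlapping genes cannot be assigned with certainty. For 6 of them the overlapping gene on the other strand has more counts: Buffy, CG13813, CG30339, Dcp-1, Jra and repo. Genes with close relatives, such as the GstD genes and RpS19a and RpS19b, are uncertain in the same way because the handling of shared reads is not given in the sources used here. One result is not reported here.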

Results

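The data are counts of RNA reads per gene in 24 libraries, each from a pool of sorted neuroblasts of the antennal lobe (AL) or the mushroom body (MB). There were 8 groups with 3 libraries each: AL at 24, 36, 50 and 84 h of larval life, and MB at 24, 50 and 84 h of larval life and at 36 h in the pupa. Total gene counts for replicates 1, 2 and 3 were 6.06, 7.31 and 6.33 M (mega-counts) for AL at 24 h, 8.19, 6.59 and 9.27 M at 36 h, 8.39, 7.77 and 8.95 M at 50 h, and 8.21, 8.01 and 6.46 M at 84 h. For MB they were 5.39, 4.78 and 4.59 M at 24 h, 3.15, 3.69 and 4.16 M at 50 h, 4.88, 4.67 and 5.02 M at 84 h, and 3.73, 4.11 and 5.83 M in the pupa. Between 10168 and 11627 genes had a count in a library. Correlations of log2 CPM across genes were 0.913 to 0.941 between libraries of a group and 0.84 to 0.934 between libraries of different groups, and genes are not independent replicates. The long noncoding RNA gene CR43283 alone took 5.15% to 19.6% of gene counts as a group mean, lowest in the pupal MB and highest in AL at 50 h.

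The series title names opposite gradients of Imp and Syp, so the comparison of larval ages asks which transcripts of AL neuroblasts changed with age. In AL neuroblasts Imp, which encodes an RNA-binding protein, averaged 32440 ± 4600 CPM (counts-per-million; SD, n = 3) at 24 h, 27500 ± 1260 at 36 h, 17660 ± 3300 at 50 h and 348 ± 47.4 at 84 h, a 93.1-fold fall from 24 to 84 h. Syp, which encodes another RNA-binding protein, averaged 1420 ± 625, 4777 ± 424, 15700 ± 988 and 28850 ± 398 CPM at the same ages, a 20.3-fold rise. The zinc finger gene chinmo fell 3.58-fold and the RNA-binding protein gene lin-28 fell 88.6-fold, while the ecdysone-induced genes Eip93F and br rose 124-fold and 6.02-fold. The log2 fold change was -6.54 ± 0.15 (SE) for Imp and 4.34 ± 0.25 for Syp, with adjusted p of 1.7e-23 and 1.9e-09 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the 3 libraries of 84 h lay to one side of the 3 libraries of 24 h for both genes. Imp (FBgn0262735) lies on chromosome X from 10690246 to 10700889 in dm3, and Syp (FBgn0038826) on 3R from 16582451 to 16631963.

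Of the 16 temporal factors tested in AL, 4 rose and 5 fell between 24 and 84 h, and the counts were 4 and 5 when adjusted over the list alone (camera adjusted p = 0.52). Imp and Syp are the study's own subject, so their place in this list is not independent evidence. The nuclear receptor gene svp fell from 778 ± 49.8 to 188 ± 35.1 CPM, and the zinc finger gene Kr from 109 ± 26.9 to 5.72 ± 4.32 CPM. Levels of lin-28 were 119 ± 35.2, 111 ± 13.5, 49.5 ± 24.2 and 1.36 ± 0.53 CPM at the 4 ages. Eip93F stood at 8.31 ± 3.29 CPM at 24 h and 1029 ± 302 CPM at 84 h, and br at 74.1 ± 2.45 and 445 ± 32.8 CPM. The grainyhead gene grh had a log2 fold change of 0.09 ± 0.12 and cas of 0.88 ± 0.58, and neither passed the test, nor did hb, mamo, nub, pdm2 and D. EcR, which encodes the ecdysone receptor, was the other riser, but its call was lost without AL 24 h replicate 1 or 2 or AL 84 h replicate 2 or 3, with log2 values of 0.50 to 0.62. Over all genes, 1584 of 10324 (15.3%) changed over the 4 AL ages.

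**Figure D1:**
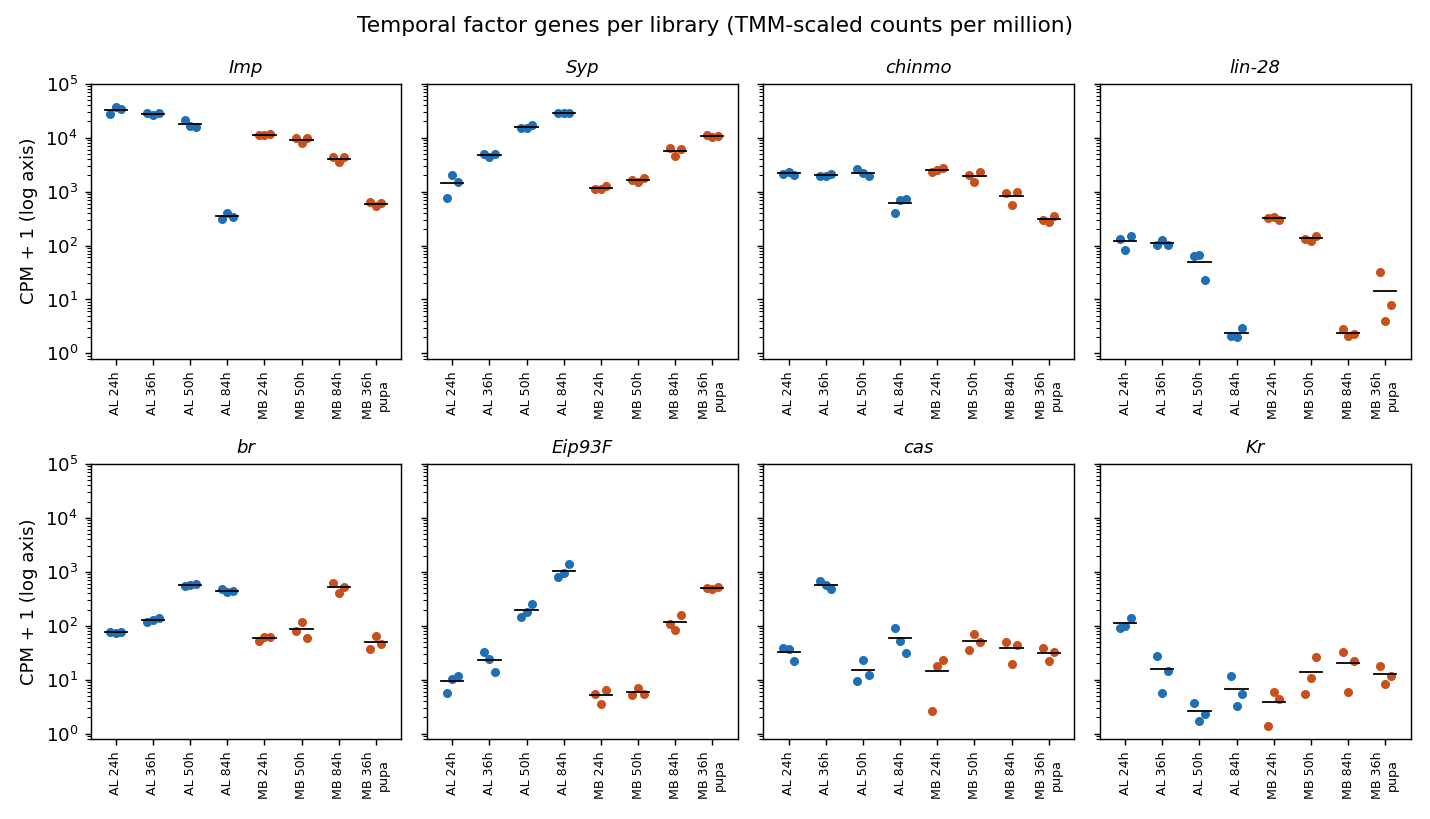
CPM plus 1 (log axis) against group for Imp, Syp, chinmo, lin-28, br, Eip93F, cas and Kr, with 1 point per library, black lines for group means, AL in blue and MB in orange. Imp falls from 32440 CPM at 24 h to 348 CPM at 84 h in AL. In MB it falls from 11290 CPM at 24 h to 590.2 CPM in the pupa, an age not sampled in AL, so the spans differ. Syp rises in both lineages.

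Outside the temporal factors, the largest AL increases from 24 to 84 h were in CG13023 (log2 6.99 ± 0.71), the noncoding RNA gene pncr002:3R (6.28 ± 0.28), CG33494, sqa, blanks, Zasp52 and CG9993. pncr002:3R rose from 54.7 ± 16.8 to 4244 ± 922 CPM. The homeobox gene Dr, a member of the MB list, rose from 1.94 ± 2.24 to 58.0 ± 9.55 CPM in AL, and the homeobox gene oc from 2.44 ± 0.70 to 72.8 ± 28.6 CPM. The largest decreases were in wntD (-6.96 ± 1.52), GstD3 (-6.72 ± 0.55), dysc (-6.07 ± 0.45), E23 (-5.07 ± 0.28), CG10924, CG33988, peb and Toll-6 (-4.66 ± 0.70). E23, an ABC transporter gene, went from 174 ± 26.7 CPM at 24 h and 429 ± 11.4 at 36 h to 5.14 ± 0.81 at 84 h. GstD3, a glutathione S-transferase gene, fell from 86.6 ± 8.59 to 0.79 ± 0.19 CPM, but reads of its close relatives cannot be excluded. For each of these genes every library at one age lay above every library at the other. Chance gives that separation in 10% of genes with 3 libraries against 3. The rule that named the largest changes required it, so it is no added evidence.

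Among metabolic and growth genes in AL, 8 of 12 glycolysis genes rose by 84 h (10 adjusted over the list alone), with a median log2 change of 0.85 (camera adjusted p = 3.9e-12, and adjusted p = 0.006 with an estimated correlation). The aldolase gene Ald rose from 204 ± 52.6 to 976 ± 44.6 CPM (2.26 ± 0.14), Tpi by 1.64 ± 0.24, Gapdh1 by 1.24 ± 0.14 and Eno by 0.83 ± 0.13 on the log2 scale. Of 43 cell cycle genes, 19 rose (21 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 2.8e-12, and adjusted p = 0.011 with an estimated correlation). They included the phosphatase gene stg (1.63 ± 0.15), CycB (1.20 ± 0.14), CycA (1.13 ± 0.11) and Mcm7 (1.10 ± 0.13). Ribosomal protein genes fell: 68 of 89 (79 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 8.2e-31, and adjusted p = 0.037 with an estimated correlation). Under spike-in and cell number scaling, which moved the median of all genes by 0.6, the list's median was 0.03. RpLP0 fell from 515 ± 37.8 to 272 ± 2.14 CPM (-0.92 ± 0.11), sta by 0.96 and RpL31 by 0.86 on the log2 scale. Of 18 ribosome biogenesis genes, 3 fell, with Fib at -0.84 ± 0.16, and Tif-IA rose by 0.75 ± 0.18 (camera adjusted p = 0.36), and the median of -0.05 became 0.57 under spike-in and cell number scaling. The 26 oxidative phosphorylation genes had a median of 0.07 (camera adjusted p = 0.52). The 2 called, ND42 (0.76) and Cyt-c-p (-0.49), each lost their call in 3 fits with 1 library left out.

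Of 21 neuroblast identity and asymmetric division genes in AL, 3 rose and 5 fell (4 and 5 adjusted over the list alone), with camera adjusted p = 0.56. The RNA-binding protein gene stau rose by 1.27 ± 0.12 and l(2)gl by 0.55, while klu fell by 0.64. Leaving out any 1 of the 6 libraries reduced the 5 fallers to between 1 and 3, and under spike-in and cell number scaling 8 genes of the list rose and its median was 0.72. In the list of 7 MB lineage transcription factors, 2 rose in AL (4 adjusted over the list alone), ey by 1.33 ± 0.22 and Dr by 4.88 ± 0.60 on the log2 scale (camera adjusted p = 0.0024, and adjusted p = 0.018 with an estimated correlation). In the list of 7 AL lineage factors, oc (4.87 ± 0.44), vvl (1.32 ± 0.30) and Lim1 rose and ems fell by 1.62 ± 0.32 (camera adjusted p = 0.12). The ems call was lost under spike-in and cell number scaling (-0.95). Lim1 (3.88) lost its call without any AL library of 24 h and without AL 84 h replicate 2 or 3, with values of 3.03 to 4.38. Of 13 Notch target E(spl) genes E(spl)m7-HLH rose and E(spl)m4-BFM fell (camera adjusted p = 0.94). The calls were lost for E(spl)m7-HLH without AL 24 h replicate 2 or 3 or AL 84 h replicate 1 (1.58 to 1.89), and for E(spl)m4-BFM without AL 24 h replicate 3 or AL 84 h replicate 1 or 3 (-5.67 to -5.57). The 4 Hox genes tested had camera adjusted p = 0.94. Of 15 ecdysone response genes, 3 rose and 2 fell, with br and Eip93F the largest risers (camera adjusted p = 0.0011, and adjusted p = 0.058 with an estimated correlation). The faller tai lost its call without AL 24 h replicate 2 (-0.34) or AL 84 h replicate 1 (-0.36). The cyclin-dependent kinase inhibitor gene dap rose from 3.50 ± 1.64 to 35.6 ± 8.58 CPM, 1 of 2 risers among 9 ganglion mother cell and newborn neuron markers (camera adjusted p = 0.043, and adjusted p = 0.21 with an estimated correlation). The other, Fas2, lost its call without AL 24 h replicate 1 or 3 or AL 84 h replicate 1 (1.45 to 1.68). Of 11 programmed cell death genes 4 rose and 1 fell, the risers including the caspase gene Ice (1.95 ± 0.27) and grim (3.59 ± 0.94), with camera adjusted p = 0.032 and adjusted p = 0.058 with an estimated correlation. The risers were 2 without AL 24 h replicate 3, and the faller Dcp-1 lost its call without AL 24 h replicate 1 or AL 84 h replicate 1 or 2 (-1.02 to -0.87).

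Markers of other cell types also moved in AL. Of 6 haemocyte markers 2 fell (4 adjusted over the list alone), with a median of -2.71 (camera adjusted p = 0.0093, and adjusted p = 0.15 with an estimated correlation). Cg25C averaged 24.3 ± 21.1 CPM at 24 h and 3.20 ± 1.85 CPM at 84 h, and its log2 change of -2.91 became -1.94 and lost its call without AL 24 h replicate 2. Hml averaged 3.04 ± 2.55 CPM at 24 h and 0.08 ± 0.14 CPM at 84 h, and lost its call without AL 84 h replicate 1 (-4.32). Of 17 neuron markers 3 fell, with futsch at -1.96 ± 0.38 (camera adjusted p = 0.13), but without AL 24 h replicate 1 or AL 84 h replicate 3 the calls of para (-1.67 to -1.60) and cpx (-1.25 to -1.14) were lost and 1 faller was left. The para call was also lost without AL 84 h replicate 1 (-1.87), and the cpx call without AL 24 h replicate 2 or 3 or AL 84 h replicate 2 (-1.16 to -0.86). Of 10 glia markers 2 fell, with nrv2 at -0.67 ± 0.15 (camera adjusted p = 0.26), and the other, Eaat1, lost its call without AL 84 h replicate 2 (-0.50). The neuron marker median moved from -0.16 to 0.39 and the glia marker median from -0.48 to 0.13 under spike-in and cell number scaling. Of 5 fat body markers Lsp1gamma rose (3.53), but lost its call without AL 24 h replicate 1 or 2 or AL 84 h replicate 2 or 3, with values of 2.96 to 3.44 (camera adjusted p = 0.94). In the heat shock and dissociation list of 15, Hsp27 rose by 0.69 ± 0.15 and Hsp83 fell by 0.62 ± 0.13, while without AL 24 h replicate 1 there were 2 fallers (camera adjusted p = 0.39). The Hsp83 call was lost under spike-in and cell number scaling (-0.01). Of 7 dosage compensation and sex genes 2 fell, with fru at -0.62 ± 0.13 (camera adjusted p = 0.11). The other, roX2, lost its call without AL 24 h replicate 1 or AL 84 h replicate 2 or 3 (-2.22 to -1.77), and the list median of -0.21 became 0.43 under spike-in and cell number scaling.

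Between 24 and 84 h, 1277 genes changed in AL, 585 higher and 692 lower at 84 h. Under spike-in and cell number scaling the median of all genes moved by 0.60 on the log2 scale and the split became 1488 higher and 150 lower, and limma on log2(TPM + 1) gave 751 higher and 489 lower. Leaving out single libraries gave 928 to 1213 genes, and 19 of the 74 called genes among those named by the rule lost their call in at least 1 of these fits.

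The same ages were compared in MB neuroblasts, and the question was again which transcripts changed. In MB, Imp fell 2.75-fold, from 11290 ± 481 CPM (SD, n = 3) at 24 h to 9187 ± 1170 at 50 h and 4097 ± 514 at 84 h. Syp rose 4.92-fold, from 1171 ± 101 to 1627 ± 145 and 5756 ± 1050 CPM. The Myc gene dm, a growth regulator, fell 4.82-fold, from 5223 ± 371 to 1080 ± 114 CPM, lin-28 fell 226-fold and chinmo 3.05-fold, while br rose 9-fold, Eip93F 28.4-fold and Ald 5.86-fold. The log2 fold change was -1.46 ± 0.12 (SE) for Imp and 2.30 ± 0.23 for Syp, with adjusted p of 4.9e-10 and 1.5e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and for both genes the 3 libraries of 84 h lay to one side of the 3 libraries of 24 h.

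Of the 16 temporal factors tested in MB, 6 rose and 4 fell (8 and 4 adjusted over the list alone), and Imp and Syp are again not independent evidence (camera adjusted p = 0.12). Levels of lin-28 were 321 ± 22.1 CPM at 24 h, 134 ± 14.3 at 50 h and 1.41 ± 0.40 at 84 h. The gene br stood at 57.4 ± 5.92, 84.8 ± 31.3 and 517 ± 109 CPM, and Eip93F at 4.12 ± 1.46, 4.86 ± 0.91 and 117 ± 37.6 CPM. grh, the grainyhead gene, fell by 0.87 ± 0.12 on the log2 scale. Kr, hb and svp rose too, but their calls did not hold when single libraries were left out. The call of hb (5.43) was lost without any of the 6 libraries (4.89 to 7.56), and those of Kr (2.77) and svp (0.81) without any of them except MB 84 h replicate 2 (2.20 to 3.46 and 0.61 to 0.92). cas had a log2 change of 1.48 and EcR of 0.56, and neither passed the test. Over all genes, 1829 (17.7%) changed over the 4 MB ages.

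The MB genes with the largest increases from 24 to 84 h included CG13023 (112-fold, 95% counting interval 30.7 to 931, from 2 counts at 24 h), Cpr76Bc (log2 6.31 ± 0.67), the chitin-related genes verm (6.30 ± 1.06) and Gasp (5.45 ± 0.93), CG34221, CG13597, Fie and ind (5.10 ± 1.05). verm averaged 0.52 ± 0.39 CPM at 24 h and 41.1 ± 17.6 CPM at 84 h, and Gasp 0.96 ± 0.96 and 41.6 ± 20.6 CPM. CG30339 had 0 counts in the 3 MB libraries of 24 h and was at least 33.1-fold higher at 84 h (20.9 ± 3.38 CPM), but it overlaps CG1902 on the other strand, which has 8.37 times its counts. The largest decreases were in lin-28 (-7.82 ± 0.74), the acetylcholine receptor subunit gene nAcRbeta-64B (-5.88 ± 0.86), Trim9 (-5.36 ± 0.76), CG30419, Prestin, ovo (-4.28 ± 0.65) and alpha-Est9 (-4.01). Trim9 fell from 42.5 ± 4.35 to 1.02 ± 0.30 CPM.

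Glycolysis genes rose in MB: 11 of 12, and 11 when adjusted over the list alone, with a median of 1.21 (camera adjusted p = 5.8e-20, and adjusted p = 0.00055 with an estimated correlation). Ald went from 296 ± 8.18 CPM at 24 h to 914 ± 147 at 50 h and 1737 ± 101 at 84 h, and PyK rose by 1.54 ± 0.15, Pglym78 by 1.48 ± 0.16 and Gapdh1 by 1.23 ± 0.14 on the log2 scale. Of 43 cell cycle genes 25 rose and 1 fell (31 and 1 adjusted over the list alone; 18 to 26 rose and at most 1 fell with 1 library left out), with a median of 0.62 (camera adjusted p = 8.7e-15, and adjusted p = 0.0041 with an estimated correlation). CycB3 rose by 1.89 ± 0.13, CycB by 1.52 ± 0.14, sub by 1.42 and CycA by 1.03 ± 0.11. With spike-in and cell number scaling 5 cell cycle and 6 glycolysis genes rose, with medians of 0.39 and 0.98. Ribosomal protein genes fell: 80 of 89 (83 adjusted over the list alone), with a median of -0.79 (camera adjusted p = 2.4e-53, and adjusted p = 0.0065 with an estimated correlation), and against genes matched for length and expression the median difference was -0.47. RpLP0 fell from 738 ± 37.0 to 337 ± 9.75 CPM, and RpS23 fell by 1.09 and RpL31 by 0.99. Of 18 ribosome biogenesis genes 4 fell, with dm at -2.27 ± 0.13 and Fib at -0.82 (camera adjusted p = 0.036, and adjusted p = 0.29 with an estimated correlation), and their median of -0.06 was 0.16 in limma on log2(TPM + 1). Of 26 oxidative phosphorylation genes 6 fell, with the cytochrome c gene Cyt-c-p at -0.95 ± 0.14 (camera adjusted p = 0.014, and adjusted p = 0.13 with an estimated correlation). The fallers were 2 without MB 24 h replicate 2 or 3 and 3 without MB 84 h replicate 1 or 2.

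Of 21 neuroblast identity and asymmetric division genes in MB, 3 rose and 7 fell (5 and 10 adjusted over the list alone), with camera adjusted p = 0.23, and 3 fell without MB 84 h replicate 2. N, the Notch receptor gene, fell by 0.97 ± 0.13, klu by 1.01 ± 0.15, and stau rose by 0.65 ± 0.12. The stau call was lost under spike-in and cell number scaling (0.4). SoxN, a neural SOX gene, rose 9.65-fold from 3.39 ± 0.34 to 33.1 ± 14.4 CPM. Of 13 E(spl) genes 2 rose and 1 fell, E(spl)m3-HLH by 2.80 ± 0.71 (camera adjusted p = 0.34). Both risers lost their calls without MB 24 h replicate 2 or 3 or MB 84 h replicate 3, with 3.07 to 3.55 for E(spl)malpha-BFM and 1.12 to 1.35 for E(spl)mgamma-HLH, which was also lost without MB 84 h replicate 1 (1.49). Of 7 MB lineage factors ey (-0.89 ± 0.21) and Rx (-1.19 ± 0.28) fell (camera adjusted p = 0.17). Of 7 AL lineage factors ct rose by 1.96 ± 0.32 to 47.8 ± 10.2 CPM and vvl by 1.78 ± 0.31 (camera adjusted p = 0.03, and adjusted p = 0.1 with an estimated correlation). Of 15 ecdysone response genes 5 rose and 3 fell, with Hr4 falling by 3.09 ± 0.39 and tai by 1.00 (camera adjusted p = 0.0084, and adjusted p = 0.13 with an estimated correlation), while 3 rose without MB 84 h replicate 1. Of 9 ganglion mother cell and newborn neuron markers 2 rose and 5 fell (camera adjusted p = 0.028, and adjusted p = 0.19 with an estimated correlation): dap rose by 2.06 ± 0.48, and Nrt, tap and fne fell by 1.19 ± 0.15, 1.34 ± 0.25 and 1.35 ± 0.21. Leaving out any 1 of the 6 libraries left 1 riser, and without MB 84 h replicate 2 there were 3 fallers. Hox genes had camera adjusted p = 0.23.

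Neuron markers fell in part in MB. Of 17 neuron markers 4 fell, with cpx at -2.69 ± 0.40 and futsch at -2.06 ± 0.39 (camera adjusted p = 0.028, and adjusted p = 0.13 with an estimated correlation). Of 10 glia markers nrv2 fell by 0.87 (camera adjusted p = 0.38), and haemocyte markers had camera adjusted p = 0.67. Of 5 fat body markers 1 rose, Lsp1gamma, whose log2 change of 4.19 became 3.66 without its call when MB 24 h replicate 2 was left out (camera adjusted p = 0.23). In the heat shock and dissociation list 2 of 15 fell, with puc at -1.11 (camera adjusted p = 0.067). There were 5 fallers without MB 24 h replicate 1 and 1 without MB 24 h replicate 2 or 3 or MB 84 h replicate 2 or 3. Of 11 cell death genes skl rose by 4.08 ± 0.87 and the apoptosis inhibitor gene th fell by 0.93 ± 0.18 (camera adjusted p = 0.46). Ice rose (1.02) but lost its call without MB 24 h replicate 2 or MB 84 h replicate 1 (0.70 to 0.82). fru rose by 0.72 ± 0.13, 1 of 2 risers among 7 dosage compensation and sex genes (camera adjusted p = 0.38), and the other, dsx, lost its call without MB 24 h replicate 2 or 3 or MB 84 h replicate 1 or 3 (2.23 to 3.14).

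In all, 1491 genes changed in MB between 24 and 84 h, 600 higher and 891 lower. Under spike-in and cell number scaling the median of all genes moved by -0.23 and the split was 210 higher and 729 lower, and in limma on log2(TPM + 1) the median moved by 0.21 and the split was 1155 higher and 567 lower. Leaving out single libraries gave 1078 to 1260 genes, and 17 of the 77 called genes among those named by the rule lost their call in at least 1 of these fits.

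The lineages were then set side by side to ask which age changes they shared. Of 542 genes that changed in both between 24 and 84 h, 496 changed in the same direction and 46 in opposite directions, against 90.7 opposite by chance. The number rising in both was 166, against 34 by chance (odds ratio 8.49, p = 3.3e-74), and the number falling in both was 330, against 59.7 by chance (odds ratio 14.73, p = 8.8e-183), by Fisher's exact test across genes, which are not independent replicates. These chance values take every tested gene as equally likely to be called. Genes with more counts or less spread are called more easily in both lineages, so the chance values may be too low. Shared risers included Syp, br, Eip93F, CG13023, pncr002:3R, Ald, Gapdh1, CycA, CycB and dap, and shared fallers Imp, chinmo, lin-28, RpLP0, Fib, klu and futsch. Under spike-in and cell number scaling the AL calls of RpLP0 (-0.31), Fib (-0.24) and klu (-0.09) and the MB call of CycA (0.79) were lost. Genes of opposite direction included ey, a PAX6 gene, which rose from 22.7 ± 7.44 to 56.9 ± 10.5 CPM in AL and fell from 171 ± 37.8 to 92.1 ± 11.2 CPM in MB. fru fell from 573 ± 91.2 to 374 ± 20.8 CPM in AL and rose from 202 ± 36.8 to 333 ± 44.2 CPM in MB. The calls of ey held under spike-in and cell number scaling (1.89 in AL and -1.16 in MB). Those of fru were lost (0.00 and 0.46), and its difference between lineages became -0.46 without a call. In limma on log2(TPM + 1) the MB call of ey was lost (-0.66, adjusted p = 0.051). With spike-in and cell number scaling 145 genes changed in the same direction in both lineages, and leaving out single libraries gave 378 to 491. Across genes the log2 changes of the lineages had Pearson's r of 0.23 and Spearman's rho of 0.26.

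**Figure D2:**
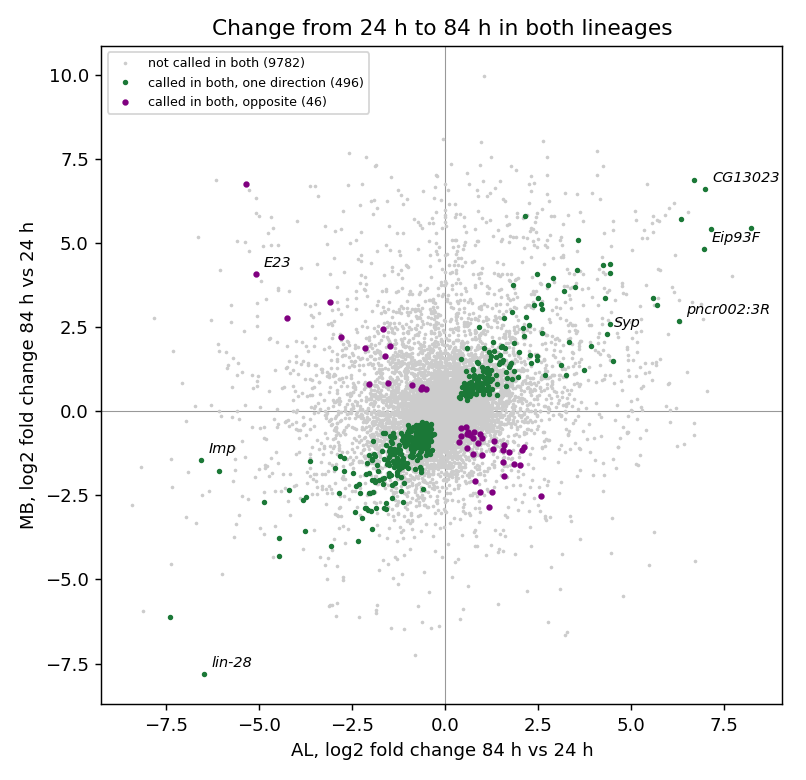
Log2 fold change from 24 to 84 h in AL (horizontal) against MB (vertical), with 1 point per gene tested. Green points are the 496 genes called in both lineages in the same direction, purple points the 46 called in opposite directions, and grey points all others.

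A test of the difference itself asked which age changes differed between AL and MB, and 486 genes differed. Imp fell by 5.08 ± 0.18 more log2 units in AL than in MB (SE, n = 3 libraries in each of 4 groups), and Syp rose by 2.05 ± 0.32 units more in AL. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2e-18 for Imp, with a 33.8-fold difference, and 0.00066 for Syp, with a 4.14-fold difference. The change of dm differed by 1.93 ± 0.17 and that of grh by 0.95 ± 0.17, both falling in MB. SoxN (-2.96 ± 0.35), svp (-2.87 ± 0.37), Kr (-7.02 ± 1.23) and ct (-2.56 ± 0.41) changed downward in AL relative to MB, and ey (2.22 ± 0.30), Hr4 (2.42) and Nrt (1.22 ± 0.21) upward. The largest upward differences also held Trim9 (7.56 ± 1.10), nAcRbeta-64B (6.37 ± 1.10), oc (5.48 ± 0.54) and ovo (5.38 ± 0.85), and the largest downward ones E23 (-9.15 ± 0.56) and GstD3 (-6.88 ± 0.69). CG30339 was among the latter too, but no size is given, because MB at 24 h had 0 counts of it. Eip93F differed by 2.13 ± 0.58 but lost its call, with values of 1.84 to 2.25, without AL 24 h replicate 1 or 2, AL 84 h replicate 2 or 3, MB 24 h replicate 1 or 3, or MB 84 h replicate 1 or 2.

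Lists that differed in their age change were few after allowing for correlation between genes. The 7 MB lineage factors had a median difference of 1.35 with 3 members called, among them ey (camera adjusted p = 3e-04, and adjusted p = 0.011 with an estimated correlation). Without MB 24 h replicate 3 the call of Dr was lost (4.31), and ey alone was left. Rx (1.90) lost its call there, without MB 24 h replicate 1 or 2, and without replicate 1 or 2 of AL 24 h, AL 84 h or MB 84 h (1.60 to 1.95). It also lost it with DESeq2 size factors (1.85), the 10 CPM filter (1.83), the replicate block (1.91), thinned libraries (1.12) and limma on log2(TPM + 1) (1.31). Of 9 ganglion mother cell and newborn neuron markers 5 were called (6 adjusted over the list alone), among them Nrt, with a median of 1.05 (camera adjusted p = 7e-05, and adjusted p = 0.036 with an estimated correlation). The called members were 2 without AL 84 h replicate 3, where elav (0.69), fne (0.95) and pros (0.65) lost their calls, and 3 without MB 84 h replicate 2. The temporal factors had 3 members called in each direction (camera adjusted p = 0.01, and adjusted p = 0.27 with an estimated correlation). Of 486 genes, 302 had the higher change in AL and 184 in MB. Under spike-in and cell number scaling the split was 993 to 86, with the median of all genes moved by 0.84, while limma on log2(TPM + 1) gave 155 to 203 with the median moved by -0.12 and DESeq2 gave 357 to 323. Leaving out single libraries gave 339 to 493 genes.

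MB neuroblasts in the pupa were compared with those at 84 h to ask what changed past the larval stage, when the MB neuroblasts were still present to be sorted. Imp fell 6.96-fold further, from 4097 ± 514 to 590 ± 54.9 CPM (SD, n = 3), a log2 change of -2.80 ± 0.13. Kr-h1, a juvenile hormone response gene, fell 27.7-fold from 147 ± 20.2 to 5.36 ± 3.75 CPM, and br fell 10.6-fold from 517 ± 109 to 48.4 ± 13.8 CPM. Eip93F rose 4.32-fold to 503 ± 14.8 CPM, and chinmo fell from 826 ± 231 to 308 ± 46.2 CPM. Ald fell 3.84-fold from 1737 ± 101 to 451 ± 51.1 CPM. Adjusted p was 1.4e-15 for Imp and 2.5e-14 for Kr-h1 (log2 -4.79 ± 0.29) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the 3 pupal libraries below the 3 libraries of 84 h for both. Syp averaged 10680 ± 549 CPM in the pupa and 5756 ± 1050 CPM at 84 h. Its log2 change of 0.89 ± 0.22 lost its call when any of the 6 libraries was left out (0.78 to 0.99).

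Other genes that rose in the pupal MB included CG10026 (log2 4.59 ± 0.75, to 60 ± 8.24 CPM), the nuclear receptor genes Hr4 (3.57 ± 0.40) and Eip75B (1.48 ± 0.24), bru-3 (3.22 ± 0.61), jim (2.46 ± 0.46) and Nrt (0.88 ± 0.15). verm, Gasp, CG11509 (-5.05), SoxN (-4.24 ± 0.31), eya (-4.16 ± 0.76), MFS3 (-3.62 ± 0.43), CR43459 and the neuroblast gene wor (-0.99 ± 0.15) fell, as did the snail family gene sna (-2.38 ± 0.34). mira, another neuroblast gene, rose (0.59) but lost its call in 4 fits with 1 library left out (0.54 to 0.58). The pupal libraries held 1 count of verm and 2 of Gasp, and the ratios of 84 h to the pupa were 657 (95% counting interval 118 to 26000) and 333 (91.9 to 2760). SoxN returned from 33.1 ± 14.4 to 1.75 ± 0.17 CPM. For grh the log2 change was -0.08 and for EcR -0.60, and neither passed the test. The lin-28 value of 3.20 lost its call without any MB library of 84 h or without pupal replicate 1 (1.86 to 3.42).

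Glycolysis genes fell together in the pupal MB: 11 of 12, and 11 when adjusted over the list alone, with a median of -1.55 (camera adjusted p = 2.2e-59, and adjusted p = 4.1e-07 with an estimated correlation). Gapdh2 fell by 2.03 ± 0.14, Pglym78 by 1.99 ± 0.17, Ald by 1.94 ± 0.14 and PyK by 1.71 ± 0.15 on the log2 scale. Of 16 temporal factors 3 rose and 3 fell (camera adjusted p = 2e-04, and adjusted p = 0.077 with an estimated correlation), with 1 riser left without any MB library of 84 h or without pupal replicate 1. Of 15 ecdysone response genes 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.94), with 1 faller left without MB 84 h replicate 1 or pupal replicate 2. Ganglion mother cell and newborn neuron markers (3 of 9 rose, Nrt among them) had camera adjusted p = 0.0017 and adjusted p = 0.077 with an estimated correlation. Neuron markers (2 of 17 rose, elav and fne, which are also on the former list) had camera adjusted p = 0.0011 and adjusted p = 0.054 with an estimated correlation. Without MB 84 h replicate 2 or pupal replicate 2 or 3 the calls of elav (0.35 to 0.53) and fne (0.68 to 0.77) were lost, and elav was also lost without MB 84 h replicate 1 (0.58). The ribosomal protein list had a median of -0.14, with camera adjusted p = 0.028 and adjusted p = 0.67 with an estimated correlation. roX1, a dosage compensation RNA, fell by 0.69 ± 0.10 and fru by 0.84 ± 0.13 (camera adjusted p = 0.0079 for their list, and adjusted p = 0.06 with an estimated correlation). A differing share of males and females between the groups is not excluded for these genes. kay, a stress-responsive transcription factor gene, fell by 1.42 ± 0.24 in the heat shock and dissociation list (camera adjusted p = 0.065).

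In the pupal MB 269 genes differed from 84 h, 75 higher and 194 lower. The count dropped to 162 without MB 84 h replicate 1, 163 without MB 84 h replicate 3, 169 without pupal replicate 1 and 172 without pupal replicate 2. Scaled by spike-in and cell number, 28 genes were higher and 72 lower, and 15 of the 43 called genes among those named by the rule lost their call there, wor, Nrt, roX1 and fru among them. Their log2 values there were -0.91, 0.99, -0.61 and -0.75, close to those of the main test, and the median of all genes moved by 0.06. Gene counts per spike-in count and cell varied 2.74-fold among the pupal libraries. A common shift therefore does not account for these losses.

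**Figure D3:**
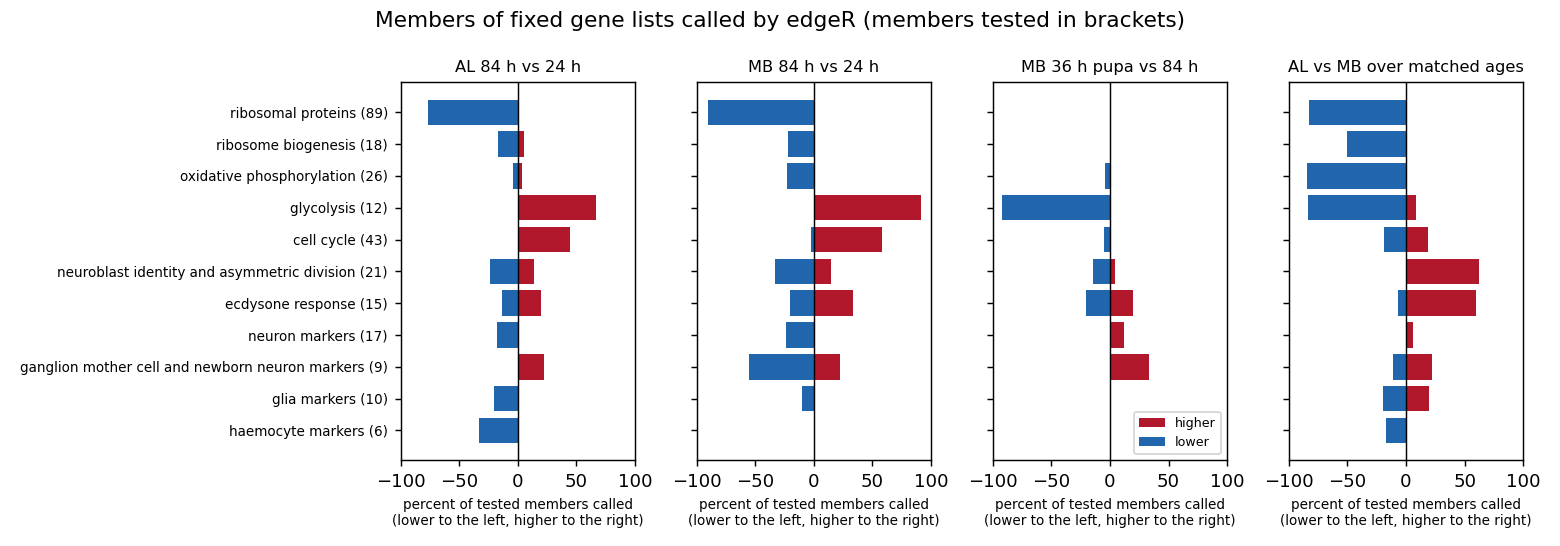
Percent of the tested members of 11 gene lists called higher (red, to the right) or lower (blue, to the left) in 4 comparisons: AL and MB at 84 h against 24 h, the pupal MB against 84 h, and AL against MB over matched ages. Glycolysis genes are higher at 84 h and lower in the pupa. The fall of ribosomal protein genes in AL, with a median of -0.58, becomes 0.03 under spike-in and cell number scaling, which is not drawn. That scaling moves the median of all genes by 0.6 in AL and by -0.23 in MB.

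AL and MB neuroblasts were compared over the matched larval ages to ask which transcripts set the lineages apart. The transcription factor genes mid, ems, slp1, slp2, SoxN, D, hkb and ct were higher in AL, and retn, Rx, tll, hbn, ap and ey in MB, in every library within each age. For genes named by the size of their difference, the naming rule required this separation. mid was higher in AL, with 333 ± 102, 186 ± 28.9 and 119 ± 29.4 CPM at 24, 50 and 84 h (SD, n = 3) and at most 0.28 CPM as a mean in larval MB. The 3 MB libraries held 2, 3 and 3 counts of mid in all at these ages, and the AL to MB ratios were 2370 (95% counting interval 657 to 19600), 715 (244 to 3470) and 623 (213 to 3020). SoxN was 76.6-fold higher in AL. In MB, retn was 112-fold higher, with 642 ± 37.1, 534 ± 77.9 and 356 ± 20.8 CPM, Rx 108-fold and tll 89.3-fold. Adjusted p was 8.8e-33 for mid, 3.1e-31 for tll (-6.48 ± 0.16) and 6.1e-27 for Rx (-6.76 ± 0.23) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 9 libraries on each side. In dm3, mid (FBgn0261963) lies on 2L from 5461641 to 5466829, retn (FBgn0004795) on 2R from 19520135 to 19542343, and tll (FBgn0003720) on 3R from 26678037 to 26680095.

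**Figure D4:**
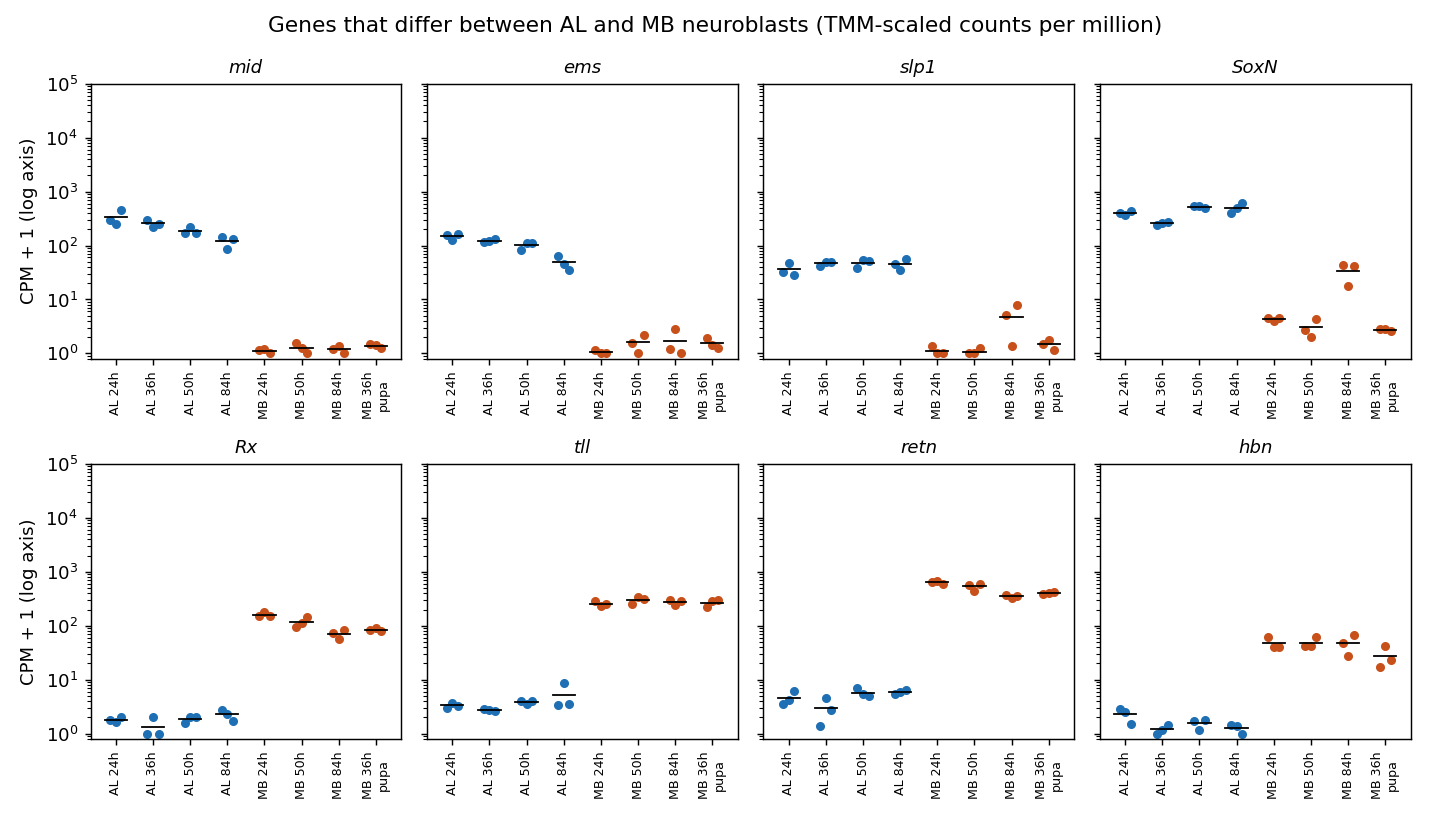
CPM plus 1 (log axis) against group for mid, ems, slp1, SoxN, Rx, tll, retn and hbn, with 1 point per library, black lines for group means, AL in blue and MB in orange. mid, ems, slp1 and SoxN are higher in AL, with SoxN at 33.1 CPM in MB at 84 h, and Rx, tll, retn and hbn are higher in MB.

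Other large differences were in CG34165 and CG4213, higher in AL, and in the actin gene Act57B (-6.07), Cyp28a5 (-5.92), CG6287, CG15414 and CG5630, higher in MB. In the list of 7 MB lineage factors 5 were higher in MB, with ey at -1.66 ± 0.13, and the homeobox gene Dr was higher in AL by 4.71 ± 0.40 on the log2 scale (median -2.41, camera adjusted p = 3.8e-26, and adjusted p = 1.2e-07 with an estimated correlation). In the list of 7 AL lineage factors 2 were higher in AL, ems (8.03 ± 0.31) and ct (4.97 ± 0.19), and 2 in MB, oc (-4.56 ± 0.23) and vnd (-3.26 ± 0.51). That list had a median of 0.19, which became -0.11 under spike-in and cell number scaling (camera adjusted p = 8.6e-05, and adjusted p = 0.003 with an estimated correlation). Among 4 Hox genes Antp was higher in MB, at least 2.78-fold at 24 h, where AL had 0 counts (camera adjusted p = 0.95).

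Of 16 temporal factors 6 were higher in AL and 1 in MB (7 and 3 adjusted over the list alone), a list that holds Imp and Syp as the study's own subject and whose median of 0.17 became -0.11 under spike-in and cell number scaling. The camera adjusted p was 5.5e-08, and adjusted p = 0.0085 with an estimated correlation, and without AL 24 h replicate 2 or AL 50 h replicate 1 there were 2 higher in MB. Imp was higher in AL at 24 h (log2 1.52 ± 0.12) and 50 h (0.94 ± 0.12) and lower at 84 h (-3.56 ± 0.14), so its mean of -0.36 over the matched ages joins opposite signs. Over the matched ages Syp was 3.89-fold higher in AL, Eip93F 8.82-fold higher, svp 5.31-fold higher and br higher by 0.97 ± 0.11. Of these svp alone was called at each age. Syp (0.28), Eip93F (1.01) and br (0.37) were not called at 24 h, and br was called only at 50 h (2.74 ± 0.19), with -0.22 at 84 h. chinmo differed by -0.15, lin-28 by -0.98 and grh by 0.17, and none of the 3 passed the test. Of 21 neuroblast identity and asymmetric division genes 13 were higher in AL (14 adjusted over the list alone), with stau at 1.29 ± 0.07, klu at 0.89 ± 0.08 and numb at 0.77 ± 0.08 (median 0.51, camera adjusted p = 2.2e-16, and adjusted p = 0.0016 with an estimated correlation), against 6 higher and 1 lower under spike-in and cell number scaling. Of 15 ecdysone response genes 9 were higher and 1 lower in AL, with EcR higher by 0.73 ± 0.12, at single ages only at 50 h (camera adjusted p = 5.2e-05, and adjusted p = 0.02 with an estimated correlation), but 2 were higher and 2 lower under spike-in and cell number scaling, where the EcR call was lost. Without AL 24 h replicate 3 or MB 24 h replicate 1, among other single libraries, 8 were higher and 0 lower. E(spl)m3-HLH (2.07 ± 0.38) and E(spl)mgamma-HLH (1.07 ± 0.27) were the 2 of 13 E(spl) genes called, against 4 without MB 24 h replicate 1 (camera adjusted p = 0.54).

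Of 89 ribosomal protein genes 74 were lower and 1 higher in AL (77 and 1 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 1.8e-33, and adjusted p = 0.017 with an estimated correlation), among them RpL39 (-1.05 ± 0.09), RpS20 and RpL10Ab (-0.79 each). Genes matched for length and expression had a median of -0.18, and the median difference to them was -0.31 (95% bootstrap interval -0.40 to -0.26). Across genes with at least 10 CPM, the log2 difference between AL and MB rose with gene length (Spearman's rho 0.26). Only the ribosomal protein list was compared with matched genes, so a length effect is not excluded for the other lists. Of 26 oxidative phosphorylation genes 22 were lower in AL (23 adjusted over the list alone), with Cyt-c-p at -1.06 ± 0.08 and ATPsyn-gamma at -0.98 (median -0.48, camera adjusted p = 5.5e-10, and adjusted p = 0.0016 with an estimated correlation). Of 12 glycolysis genes 10 were lower and 1 higher in AL, with Gapdh1 at -1.11 ± 0.08, Pglym78 at -1.06 and Pgi at -0.87 (median -0.64, camera adjusted p = 4.1e-08, and adjusted p = 0.0085 with an estimated correlation). Of 18 ribosome biogenesis genes 9 were lower in AL, with Fib at -0.52 and dm at -0.38 ± 0.07 (camera adjusted p = 0.0063, and adjusted p = 0.15 with an estimated correlation), and 4 were lower without MB 84 h replicate 2. Cell cycle genes split, with 8 of 43 higher and 8 lower in AL (camera adjusted p = 0.7): barr was higher by 0.86, while geminin (-0.48) and Orc1 (-0.57) were lower. Of 7 dosage compensation and sex genes 3 were higher in AL, with roX1 at 0.81 ± 0.06 and fru at 0.80 ± 0.08 (camera adjusted p = 0.0078, and adjusted p = 0.026 with an estimated correlation). The groups were not defined by sex, so a differing share of males and females is not excluded for this list. Of the neuron markers cac was higher in AL (0.96, camera adjusted p = 0.69), and of 6 haemocyte markers Hml was lower (-2.87 ± 0.66, camera adjusted p = 0.62). Of 10 glia markers 2 were higher in AL, nrv2 (0.29) and loco (0.42), and 2 lower, Eaat1 (-0.65) and alrm (-1.55), with camera adjusted p = 0.95. The calls of nrv2 (-0.03) and loco (0.12) were lost under spike-in and cell number scaling, and that of alrm in 9 fits with 1 library left out (-1.53 to -1.18). Of 9 ganglion mother cell and newborn neuron markers tap was lower in AL (-0.67) and pros (0.21) and Nrt (0.23) were higher (camera adjusted p = 0.95). With 1 library left out the call of pros was lost in 8 fits (0.17 to 0.21) and that of Nrt in 10 (0.17 to 0.24). Both were -0.10 and uncalled under spike-in and cell number scaling. In the heat shock and dissociation list 3 of 15 were lower in AL, with kay at -0.84 (camera adjusted p = 0.54). Of 11 cell death genes W was lower in AL, at least 10.4-fold at 50 h, where AL had 0 counts, rpr was lower (-1.15) and Ice higher (0.64), with camera adjusted p = 0.69. The call of rpr was lost in 9 fits with 1 library left out (-1.11 to -0.85), and that of Ice under spike-in and cell number scaling (0.33). Of 5 fat body markers 1 was higher in AL (camera adjusted p = 0.91).

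Over the matched ages 2260 genes differed, 1153 higher in AL and 1107 higher in MB. The number was 1120 at 24 h (490 higher in AL), 1170 at 50 h (660 higher) and 792 at 84 h (456 higher). With spike-in and cell number scaling 237 were higher in AL and 1785 in MB over the matched ages, with splits of 92 to 3997 at 24 h, 593 to 117 at 50 h and 81 to 254 at 84 h, and the median of all genes moved by -0.31, -1.07, 0.36 and -0.23 in turn. In limma on log2(TPM + 1) the split was 598 to 474 at 24 h, where the median moved by 0.10. Without MB 50 h replicate 2 the count at 50 h was 762, and without AL 84 h replicate 3 the count at 84 h was 513.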

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

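The length test of ribosomal protein genes and the counts of other splits of the libraries were planned before their results were seen; the marker, library and spike-in tests in this part were chosen only after. For the marker and spike-in tests, what would count for or against the cause was also set anew once their values were known. Both causes are now left open, where the first rule had counted against tracheal or epidermal cells and for uneven spike-in. A scaling test of ribosomal protein genes, also chosen after, was dropped because scaling shifts all genes alike.

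The age changes of AL and MB neuroblasts differed in a direct test of the difference, with 486 genes called. The named genes with the largest differences, as log2 change in AL minus that in MB from 24 to 84 h, were Trim9 (7.56), nAcRbeta-64B (6.37), Dr (5.53), oc (5.48) and ovo (5.38) upward and E23 (-9.15), Cpr76Bc (-7.34), Kr (-7.02) and GstD3 (-6.88) downward. CG30339 also differed, but its fitted value of -8.93 is no size or bound, because MB at 24 h had 0 counts of it. Against the floor it was at least 33.1-fold higher in MB at 84 h than at 24 h. The call of Dr was lost without MB 24 h replicate 3 (4.31) and that of Cpr76Bc without AL 24 h replicate 1 (-5.17). The temporal factors that differed were Imp (-5.08), Syp (2.05), Eip93F (2.13), svp (-2.87), grh (0.95) and Kr, given above. The call of Eip93F was lost when single libraries were left out (1.84 to 2.25), namely AL 24 h replicate 1 or 2, AL 84 h replicate 2 or 3, MB 24 h replicate 1 or 3, and MB 84 h replicate 1 or 2. At the level of lists, the difference had a camera adjusted p of 0.01 for temporal factors, 3e-04 for MB lineage transcription factors, 0.00059 for ribosomal proteins, 0.003 for oxidative phosphorylation, 0.037 for glycolysis, 7e-05 for ganglion mother cell and newborn neuron markers, 0.027 for haemocyte markers, and 0.021 for dosage compensation and sex. With an estimated correlation the adjusted p stayed under 0.05 for the MB lineage factors (0.011) and the ganglion mother cell and newborn neuron markers (0.036), and was 0.27, 0.59, 0.095, 0.37, 0.27 and 0.095 for the other 6 in the same order.

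Counts of genes were also taken for other splits of the same libraries with edgeR. Of 60 splits, 1 (the real one) gave as many genes for change over the AL ages (1584, highest other 595). The same held for change over the MB ages (1829, highest other 216) and for AL against MB over the matched ages (2260, highest other 205). In these comparisons the share was under 0.05, which argues against a random allotment of single libraries. The splits take each library as independent. They cannot exclude differences between cultures or sorts that the libraries of a group may share. For the difference between lineages the real split gave 486 genes and the highest other 464. Its splits mixed libraries across both age and lineage, so they cannot test whether the age change differed. For the 496 genes changed in the same direction in both lineages, 1 of 100 splits gave as many and the highest other gave 0. Each of these paired 1 of 10 splits of AL with 1 of 10 splits of MB. The other splits of each lineage called at most 1 gene, so almost no shared genes could arise. The paired splits therefore cannot test whether the sharing exceeded chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other values were 1277 and 1 for AL at 84 h against 24 h, 1491 and 1 for MB at 84 h against 24 h, 269 and 2 for the pupal MB against 84 h, 1120 and 0 for AL against MB at 24 h, 1170 and 0 at 50 h, and 792 and 0 at 84 h.

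Ribosomal protein genes were lower at 84 h than at 24 h in both lineages, with medians of -0.58 in AL and -0.79 in MB. A bias by gene length is argued against by genes matched for length and expression, from which the list still differed by a median of -0.55 in AL and -0.47 in MB. In MB the matched genes fell too, with a median of -0.36, so part of the list's fall there was shared by genes of like length and expression. Scaling by spike-in and cell number shifts all genes alike, by 0.60 in AL and -0.23 in MB. The list medians of 0.03 and -1.02 under it carry that shift, so they cannot test why this list differs from other genes, and whether ribosomal protein transcripts fell per cell in AL stays open. A change with age, which the design names, also stays open and untested.

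The genes verm, Gasp and Cpr76Bc, known from chitin-forming tissues, and the transcription factor gene Sp1 were highest or near their highest in MB at 84 h, with 41.1, 41.6, 95.5 and 12.4 CPM. Tracheal or epidermal cells carried through the sort of GFP-positive cells may account for verm and Gasp and are not excluded. Of 11 tested markers of such cells 1 (knk) was called higher at 84 h, with 10.7 CPM against 2.54 CPM at 24 h and 11.6 CPM at 50 h. The median log2 change of the markers was 1.16, from -2.71 (uif) to 3.34 (obst-B), with serp at 2.05 and kkv at 1.76. Cpr76Bc averaged 37 CPM in MB at 50 h and 115 CPM in the pupa. There verm averaged 0.916 and 0.078 CPM and Gasp 0.474 and 0.156 CPM. Cells in the 84 h sort alone therefore leave the levels of Cpr76Bc at these other ages unaccounted for. In AL, Gasp averaged 18.8 CPM at 50 h and 6.23 CPM at 84 h, so it was not confined to MB at 84 h. The median marker level at 84 h was 4.99 CPM and the highest 11.9 CPM (kkv), and the level such cells would bring is not known from these data. A single library as the source is argued against by the highest ratio between the 3 libraries of 84 h, 3.09 (Gasp). Each of these genes was lowest in MB 84 h replicate 2. There verm stood at 24.8 CPM and Gasp at 17.9 CPM, against 59.7 and 55.4 CPM in replicate 1 and 38.7 and 51.5 CPM in replicate 3. This joint variation does not tell carried-over cells from neuroblasts. Expression by the MB neuroblasts at this age stays open as well and was not tested.

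Gene counts per spike-in count and cell were 2.82 in MB at 24 h and 1.37 in AL at 24 h, a ratio of 2.05. The libraries of the 2 groups did not overlap (2.46 to 3.17 against 1.19 to 1.47), and the highest to lowest ratio within them was at most 1.29, which goes against unevenness from library to library. Such unevenness did reach 2.74 within the pupal MB, and an amount of spike-in or a cell count that was off for a whole group cannot be told apart from the group, because each group was a sort of its own age and lineage. More RNA per MB neuroblast at 24 h would give the same ratio and stays open. The comparisons of AL with MB at 24 h that were scaled by spike-in rest on this ratio.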

How the results depend on the processing

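Under spike-in and cell number scaling the counts that moved by over 1.5 times were 3866 genes for change over the MB ages (1829 in the main test), 939 for MB at 84 h against 24 h, 100 for the pupal MB, 4089 for AL against MB at 24 h, 710 at 50 h, 335 at 84 h, 1079 for the difference between lineages and 145 for the shared changes. With spike-in scaling without cell numbers, chosen after the data were seen because of the repeated cell numbers, they were 4692, 967, 115, 4401 (24 h), 391 (84 h), 1233 and 164. These scalings set the level of all genes by the spike-in, which by construction shifts every gene of a library together. Values that changed sign under spike-in and cell number scaling were, for AL at 84 h against 24 h, Nop60B (0.01), CG8801 (0.21), Cyt-c-p (0.12), ftz-f1 (0.01), tai (0.05) and Eaat1 (0.06), for AL against MB nrv2 (-0.03), pros (-0.10) and Nrt (-0.10), and for the difference between lineages CycB3 (0) and Gapdh2 (0.10). Without cell numbers they were Nop60B (0.02), CG8801 (0.21), Cyt-c-p (0.13), ftz-f1 (0.02), tai (0.06), Eaat1 (0.07), Hsp83 (0), fru (0.01), pros (-0.07), Nrt (-0.06) and Gapdh2 (0.07). The cause was not tested beyond this construction.

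Leaving out each library gave 1320 to 1602 genes for change over the AL ages, 1530 to 1781 for the MB ages, 928 to 1213 and 1078 to 1260 for 84 h against 24 h in AL and MB, 162 to 262 for the pupal MB, 2053 to 2350 for the matched ages, 817 to 1079, 762 to 942 and 513 to 691 at 24, 50 and 84 h, 339 to 493 for the difference between lineages and 378 to 491 for the shared changes. Each of these fits has 1 library fewer by construction, and the cause was not tested further. The replicate block gave 1246 and 1496 genes for 84 h against 24 h in AL and MB. Replicate numbers did not pair the samples: after group means were removed, the 84 pairs of libraries with the same number had a median correlation of 0.002, against -0.001 for other pairs, and 9 of 24 libraries correlated best with their own number. With DESeq2 size factors, DESeq2, no filter, a 10 CPM filter, only the groups compared, the replicate block, limma on log2(TPM + 1), the fit without ribosomal RNA genes and CR43283, and the thinned libraries, every total stayed within 1.5 times. Counts per direction moved further. With limma on log2(TPM + 1) they were 1155 higher and 567 lower for MB at 84 h against 24 h (600 and 891 in the main test) and 155 higher for the difference between lineages (302). With DESeq2 118 were higher in the pupal MB (75), 520 lower for AL against MB at 84 h (336) and 323 lower for the difference (184), and with no filter the first and last were 114 and 285. The cause was not tested. Of the single values, 576 of 586 kept their direction and side of the threshold with DESeq2 size factors, 462 of 515 with limma on log2(TPM + 1), 426 of 515 with spike-in and cell number scaling and 4561 of 4902 with 1 library left out. Of the list calls, 37 of 71 held with an estimated correlation and 66 of 71 with fry. Depth limits calls of genes under about 1 CPM, where 3 counts are 0.324 to 0.952 CPM.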

Other observations

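The values in this part come from tests chosen after the data were seen, except the 4-age test and the lists, which were planned. List p-values between neighbouring ages were adjusted over the 20 lists within each step. Family p-values were adjusted over the 14 families within each comparison.

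Ribosomal protein genes did not move in 1 direction through the AL ages. From 24 to 36 h 55 of 89 rose and 1 fell, with a median of 0.59 (camera adjusted p = 2.9e-50, and adjusted p = 0.024 with an estimated correlation), and from 36 to 50 h 68 fell, with a median of -0.91 (adjusted p = 0.00018 with an estimated correlation). Under spike-in and cell number scaling, which moved the median of all genes by 0.15 and 0.27, these medians were 0.75 and -0.63, with 22 genes higher and 8 lower. In MB the main step lay between 50 and 84 h, with 65 of 89 lower and a median of -0.56, against a median of -0.22 between 24 and 50 h. Under spike-in and cell number scaling these medians were 0.23 and -1.25, where all genes moved by 0.77 and -1.01, so which step held the larger fall depends on the scaling. The castor gene cas peaked in AL at 36 h, at 569 ± 104 CPM against 31.2 ± 8.94 at 24 h and 14.2 ± 7.40 at 50 h (SD, n = 3). Its log2 change was 4.18 ± 0.63 (adjusted p = 6.5e-04) and then -5.33 ± 0.67 (adjusted p = 6.4e-05) in edgeR's quasi-likelihood test, with the 3 libraries of 36 h above the other AL libraries. CR43283 rose from 24 to 36 h (0.87 ± 0.17) and fell from 50 to 84 h in AL (-1.53 ± 0.17). In MB, 11 of 12 glycolysis genes rose between 24 and 50 h, with a median of 1.17 (adjusted p = 2.5e-05 with an estimated correlation), but under spike-in and cell number scaling 1 was higher and 1 lower, with a median of 0.14 and all genes moved by -1.01.

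Further gene families were picked by name after the data were seen, 14 in all. In AL from 24 to 84 h tubulin genes had a median of 0.32 with 2 of 9 higher, betaTub60D by 2.49 (camera adjusted p = 0.0095, and adjusted p = 0.046 with an estimated correlation), and nuclear pore genes a median of 0.35 with 5 of 16 higher, Nup154 by 0.80 (camera adjusted p = 0.0018, and adjusted p = 0.046 with an estimated correlation). Glutathione S-transferase genes had a median of -0.93 with 4 of 30 lower and 1 higher, GstD1 by -1.28 (camera adjusted p = 0.00027, and adjusted p = 0.024 with an estimated correlation), and reads shared between these close relatives are not excluded. In MB that family had a median of -0.27 (camera adjusted p = 0.37, and adjusted p = 0.51 with an estimated correlation), and nuclear pore genes one of 0.25 (camera adjusted p = 0.028, and adjusted p = 0.2 with an estimated correlation). In MB from 24 to 84 h tubulin genes had a median of 0.28 with 3 of 9 higher, betaTub60D by 3.35 (adjusted p = 0.027 with an estimated correlation). No other family test in the 5 comparisons stayed under 0.05 with an estimated correlation.

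Of the genes that changed over the 4 ages in AL, 424 had their highest mean at 24 h, 354 at 36 h, 243 at 50 h and 563 at 84 h. In MB the numbers were 934 at 24 h, 222 at 50 h, 304 at 84 h and 369 in the pupa. Across 5324 genes with at least 10 CPM, Spearman's rho of the log2 change with gene length was -0.27 for AL at 84 h against 24 h, -0.16 for MB, 0.26 for AL against MB over the matched ages and -0.04 for the pupal MB against 84 h. With GC content it was 0.09, 0.18, -0.18 and 0.06 in turn, and genes are not independent replicates.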
